A study of Homo sapiens with 30 samples.

How the data were processed

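Expression was measured by stranded paired-end RNA sequencing of HepG2 cells, per the labels' protocols, in 30 libraries of 13 groups. The authors deposited a table of expected counts per gene for several batches, with 60675 Ensembl gene rows, and 240 of its columns belonged to no sample used here and were not read. Per the submitters' processing notes, the tools were FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a and RSEM 1.3.3 with hg38 and GRCh38 named as builds. The annotation release is not given in the sources used here. The deposited expected counts come from sharing reads among transcripts, so 8.56% of values were not whole, and reads that fit several near-identical genes are divided by estimate. Genes with close paralogs, pseudogenes or readthrough partners, such as the AKR1C, UGT1A, metallothionein, HSPA1 and GOLGA8 families, are therefore uncertain.

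The sample labels give the vehicle as 0.1% DMSO and the series design text as 2%; the sample value is used here. The design text also says that extracts with a lower toxicity limit were given at other doses; the doses here are those of the labels. The wortmannin control and the other replicates of Samul-tang and Sagunja-tang were not analysed here. Groups, tests, gene lists and alternatives were fixed before the data were examined, except where stated.

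The expected counts were rounded to whole numbers. Genes were kept by filterByExpr at its defaults (minimum count 10, minimum total 15), which left 16083. TMM factors were used, and edgeR 4.0.16 (R 4.3.3) fitted 1 quasi-likelihood model with robust settings to the 27 libraries of the 10 groups with more than 1 library, with 17 residual degrees of freedom and a biological coefficient of variation of 5.47%. The 16 comparisons were tested two-sided with glmQLFTest, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Log2 fold changes are given with a standard error taken as the absolute log2 fold change divided by the square root of F. Levels are CPM with TMM factors, as mean ± SD. Gene symbols came from a table of Ensembl identifiers that matched 56558 rows, 41209 of them with a symbol. Positions are from GENCODE 29 on GRCh38.

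There were 35 gene lists fixed in advance, with 626 symbols, of which 609 matched a row. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01 and adjusted over the lists of each comparison, and again with an estimated correlation. The report names, per high dose against vehicle and for Sibjeondaebo-tang high against Palmul-tang high, up to 8 genes each way with the largest log2 fold change among called genes with a mean log2 CPM of 2 or more, separated replicates and a gene symbol that is no clone or LINC name. It also names up to 4 members per list with the smallest adjusted p, the called genes of comparisons with few calls, and 9 genes always given at the high doses. Some genes that this rule takes are not reported here.

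The scripts were tested on simulated counts with 200 seeded genes. For Palmul-tang high against vehicle, the test recovered 32% of genes changed 1.2-fold, 88% at 1.5-fold, 96% at 2-fold and 100% at 3-fold, with 6 of 15671 unchanged genes called. For Samul-tang high against vehicle it recovered 32%, 86%, 94% and 100%, with 12 of 15643 called, and for Sibjeondaebo-tang high against Palmul-tang high 42%, 80%, 92% and 94%, with 6 of 15667 called. Replicates were compared before averaging. The 24 pairs differed by 1.78 to 9.87 times counting noise, so none was a library deposited more than 1 time. The highest value was that of Samul-tang medium replicates 2 and 3, and the next highest was 4.21, for Palmul-tang low replicates 1 and 2.

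Sagunja-tang was described by log2 ratios of CPM with a prior count of 2. The overlap of calls between formulas was compared with independent lists and with 20 simulations of unchanged groups against the same vehicle libraries. The alternatives were DESeq2 1.42.0, median-ratio factors in edgeR, no filter, a fit of the compared groups alone, the replicate number as a block, each replicate left out in turn, an estimated correlation in camera and a prior count of 0.5. An offset for GC content and transcript length, a prior count of 0.5 for Sagunja-tang high against low, and these alternatives for the calls shared at all 9 doses and in high against low were added after seeing the data.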

Results

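RNA sequencing profiled HepG2 cells, a human liver cancer cell line, after 24 h with extracts of tonifying herbal formulas. The 30 libraries held 3 vehicle libraries and 27 extract libraries at 500 (high), 100 (medium) or 20 (low) µg/mL. Palmul-tang and Sibjeondaebo-tang had 3 libraries per dose, Samul-tang had 2 and Sagunja-tang had 1. In traditional use, Palmul-tang combines the herbs of Samul-tang and Sagunja-tang, and Sibjeondaebo-tang adds Astragalus and cinnamon to Palmul-tang. Totals ran from 21570416 to 37707232 expected counts per library. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. The vehicle libraries carried a label prefix of their own. Samul-tang and Sagunja-tang shared another prefix, and Palmul-tang and Sibjeondaebo-tang shared a further one, so comparisons with vehicle cannot be told apart from a difference between these library sets. The sample titles name the same batch, BatchE, for all 30 libraries, and what the prefixes stand for is not given. Comparisons of high with low dose, and of Sibjeondaebo-tang with Palmul-tang, lay within a set. On the first principal component, which held 13.6% of the variance, the vehicle libraries lay from -33.3 to -31.3 and the others from -11.4 to 21.1. An unnamed gene on chromosome 21 (ENSG00000280800, 8210384 to 8211306, GRCh38) is annotated as a lincRNA, and which RNA its reads come from was not tested. It had a level of 964 ± 170 CPM (counts scaled to library size, SD, n = 3) in vehicle and at most 121 CPM in any extract library. Further annotated genes, such as ENSG00000280614, had the same counts in every extract library, so reads were divided among near-identical copies and the level is uncertain. Mitochondrial transcripts took 12.4% to 14.5% of counts in vehicle and 17.2% to 19.4% in Sibjeondaebo-tang high. Over all extract libraries they ran from 11.2% in Samul-tang medium replicate 3 to 19.7% in Sibjeondaebo-tang medium replicate 3. The nuclear RNA MALAT1 was at 391 to 426 CPM in vehicle and 235 to 336 CPM in the extract libraries, and RN7SL2 at 16.6 to 31.01 and 1.43 to 16.4 CPM.

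Palmul-tang high was compared with vehicle to find which transcripts changed at the highest dose. CYP1A1, a dioxin-inducible cytochrome P450 (chromosome 15, 74719542 to 74725610), rose from 11.3 ± 1.51 CPM (SD, n = 3) to 178 ± 7.73 CPM (SD, n = 3), a log2 fold change of 4.00 ± 0.087 (SE) with an adjusted p of 7.18e-23. Targets of the oxidant-sensing factor NRF2 rose together, with 19 of 22 measured members higher and none lower. Among them were AKR1B10 (chromosome 7, 134527592 to 134541408; log2 1.48 ± 0.06), NQO1 (chromosome 16, 69706996 to 69726951; 0.87 ± 0.053), AKR1C2 (0.97 ± 0.064) and GCLM (0.89 ± 0.067), which encode detoxifying enzymes and a glutathione synthesis subunit. Cholesterol synthesis genes fell, with 18 of 24 lower and 1 higher, led by HMGCS1 (-0.53 ± 0.045) and TM7SF2 (-0.63 ± 0.058). Of 27 genes of S phase and DNA replication, 16 fell, including E2F1 (-0.54 ± 0.055) and MCM3 (-0.37 ± 0.042).

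Stress-related lists were also higher in Palmul-tang high than in vehicle. Not every gene in them followed the dose, since HSPA1A was at 124.5 CPM with the high and 131.1 CPM with the low dose. Heat shock protein genes rose in 11 of 16 cases, with HSPA1A at log2 1.09 ± 0.058 and HSPA8 at 0.83 ± 0.053. ER chaperone genes rose in 12 of 19 cases, including MANF (0.42 ± 0.059) and DNAJB11 (0.38 ± 0.047). Glycolysis and hypoxia response genes rose in 18 of 25, with NDRG1 at 0.96 ± 0.09, PDK1 at 0.76 ± 0.053 and VEGFA at 0.58 ± 0.054. AHR targets rose in 6 of 9 members, and immediate early genes rose in 11 of 21, led by DUSP6 (0.74 ± 0.049) and EGR1 (0.68 ± 0.079). Integrated stress response genes rose in 14 of 22 and fell in 2, with STC2 at 0.75 ± 0.053, but the list's adjusted p was 0.075 with an estimated correlation. Fatty acid synthesis genes fell in 9 of 18 and rose in 1, including DGAT2 (-0.55 ± 0.05), with an adjusted p of 0.0771 with an estimated correlation. Metallothionein genes fell in 4 of 9, including MT1F (-0.90 ± 0.127), with an adjusted p of 0.346 with an estimated correlation. Mitochondrially encoded genes rose in 8 of 13, with an adjusted p of 0.404 with an estimated correlation. Adjusted over the list alone, 20 NRF2 targets, 21 glycolysis and hypoxia genes and 13 ER chaperone genes rose, and 20 cholesterol genes and 17 replication genes fell.

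Other named genes higher in Palmul-tang high were PFKFB3, a regulator of glycolysis (log2 2.02 ± 0.224), TMCC1 (1.77 ± 0.067), SPP1, which encodes osteopontin (1.47 ± 0.092), and PPP2R2C (1.45 ± 0.12). Named genes that were lower were KNG1 (-1.10 ± 0.085), ANKRD1 (-1.08 ± 0.103), DTX4 (-1.05 ± 0.084), the Wnt antagonist DKK1 (-1.03 ± 0.059) and EXOC3L4 (-1.01 ± 0.117). CFAP298-TCP10L (3.04 ± 0.726), RN7SL1 (-2.34 ± 0.55), RN7SL2 (-3.11 ± 0.751) and RPL7AP6 (-1.15 ± 0.232) also passed, but they share sequence or reads with other genes and are uncertain. HMOX1 was higher (0.34 ± 0.06), ALB (-0.40 ± 0.051) and MT1X (-0.70 ± 0.124) were lower, and CDKN1A (0.06, adjusted p 0.455), DDIT3 (-0.23, adjusted p 0.0547) and CYP3A4 (-0.16, adjusted p 0.82, 0.237 CPM) did not pass. In all, 5118 of 16083 tested genes were called, 2616 higher and 2502 lower, and 281 changed by at least 1 on the log2 scale.

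The lower doses of Palmul-tang were compared with vehicle in the same fit. At the medium dose 1859 genes were higher and 1735 lower, and at the low dose 1844 were higher and 1883 lower. CYP1A1 followed the dose, at log2 1.73 ± 0.09 with the medium dose. Glycolysis and hypoxia genes rose in 20 of 25 members at the medium dose (median log2 0.51, PDK1 0.93 ± 0.052, PFKFB4 0.93 ± 0.078) and in 16 of 25 at the low dose, where the adjusted p was 0.387 with an estimated correlation. HSPA1A rose by a similar amount at each dose, with log2 1.02 ± 0.058 at the medium and 1.16 ± 0.058 at the low dose. Replication genes fell in 16 of 27 at the medium and 17 of 27 at the low dose, about as many as at the high dose. NRF2 targets were not called as a list at either dose. The medium count was 2309 without Palmul-tang medium replicate 3, and the low count was 2392 without vehicle replicate 2.

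Sibjeondaebo-tang high against vehicle was examined for the effect of the formula with the added herbs. CYP1A1 rose to 137 ± 20.1 CPM (SD, n = 3; log2 3.62 ± 0.087, adjusted p 9.42e-22), and 19 of 22 NRF2 targets rose, including AKR1B10 (1.23 ± 0.06), NQO1 (0.76 ± 0.053) and GCLC (0.50 ± 0.04). Heat shock genes rose in 15 of 16 members, with HSPA1A at 1.11 ± 0.058, and ER chaperone genes rose in 14 of 19. Replication genes fell in 17 of 27 and rose in 1, with E2F2 at -0.91 ± 0.088. The following lists were called with the preset correlation only. Cholesterol synthesis genes fell in 13 of 24 and rose in 2 (LSS -0.66 ± 0.054; adjusted p = 0.0665 with an estimated correlation). Integrated stress response genes rose in 14 of 22 and fell in 1 (ASNS 0.73 ± 0.05, CEBPB 1.23 ± 0.086; adjusted p = 0.0526 with an estimated correlation). Glycolysis and hypoxia genes rose in 20 of 25 and fell in 1, and immediate early genes rose in 10 of 21, each with an adjusted p of 0.0665 with an estimated correlation. Metallothionein genes fell in 5 of 9 (MT1X -1.03 ± 0.127, MT1F -1.05 ± 0.129), mitochondrially encoded genes rose in 12 of 13, with mitochondrial transcripts at 17.2% to 19.4% of counts beside 12.4% to 14.5% in vehicle, and fatty acid synthesis genes fell in 9 of 18 and rose in 1 (MLXIPL -0.84 ± 0.066), each with an adjusted p of 0.21 with an estimated correlation.

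Further named genes higher in Sibjeondaebo-tang high were PFKFB3 (log2 2.01 ± 0.224), TMCC1 (1.61 ± 0.067), MT-ATP8 (1.51 ± 0.341), SPP1 (1.33 ± 0.092) and PPP2R2C (1.27 ± 0.122). Lower were EXOC3L4 (-1.68 ± 0.126), CCDC144NL (-1.43 ± 0.118), NPEPL1 (-1.37 ± 0.104), COL7A1 (-1.34 ± 0.13), CSAD (-1.23 ± 0.137) and ATG16L2 (-1.23 ± 0.121). The readthrough gene RPS10-NUDT3 (1.78 ± 0.579) and RN7SL1 (-1.38 ± 0.5) passed but lost the call without some replicates, with adjusted p values up to 0.118 and 0.159. HMOX1 was higher (0.32 ± 0.06), ALB (-0.34 ± 0.051) and DDIT3 (-0.41 ± 0.092, adjusted p 0.000811) were lower, and CDKN1A (0.02, adjusted p 0.845) and CYP3A4 (-0.18, adjusted p 0.772) did not pass. In all, 3109 genes were higher and 2682 lower, a share of 53.7% higher that became 63.8% with an offset for GC content and length. With the medium dose 2464 were higher and 2388 lower, and with the low dose 1852 were higher and 1844 lower. CYP1A1 was at log2 1.79 ± 0.089 with the medium dose. Without vehicle replicate 2 the low count was 2284. Sibjeondaebo-tang low replicate 3 held fibroblast marker transcripts, with COL1A1 at 8.3 CPM, and without it the low count was 2615.

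Samul-tang high against vehicle rested on 2 extract libraries. CYP1A1 rose to 88.7 ± 0.530 CPM (SD, n = 2; log2 2.99 ± 0.092, adjusted p 5.79e-19). NRF2 targets rose in 21 of 22 members, with AKR1B10 at 1.44 ± 0.064, AKR1C2 at 1.15 ± 0.069 and AKR1C1 at 0.97 ± 0.073. Cholesterol synthesis genes fell in 14 of 24 (HMGCS1 -0.52 ± 0.051) and replication genes in 16 of 27 (E2F2 -0.80 ± 0.095). Heat shock genes rose in 9 of 16, glycolysis and hypoxia genes in 17 of 25 (NDRG1 0.99 ± 0.097), AHR targets in 5 of 9 and integrated stress response genes in 11 of 22, of which 1 other member fell. Fatty acid synthesis genes fell in 10 of 18 and rose in 1, led by DGAT2 (-0.44 ± 0.055). ER chaperone genes rose in 6 of 19, with an adjusted p of 0.0703 with an estimated correlation. Mitochondrially encoded genes rose in 5 of 13, with an adjusted p of 0.313 with an estimated correlation.

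Among further genes in Samul-tang high, PFKFB3 (log2 1.92 ± 0.238), TMCC1 (1.49 ± 0.072), PPP2R2C (1.19 ± 0.131) and SPP1 (1.13 ± 0.1) were higher. ANKRD1 (-1.25 ± 0.115), SLC2A4, an insulin-responsive glucose transporter (-0.97 ± 0.093), SFT2D2 (-0.87 ± 0.132), EXOC3L4 (-0.86 ± 0.126), CCDC144NL (-0.81 ± 0.119), SGK1 (-0.80 ± 0.084) and SCNN1A (-0.79 ± 0.089) were lower. NQO1 was at 0.74 ± 0.058, HMOX1 at 0.42 ± 0.066, ALB at -0.29 ± 0.057 and MT1X at -0.57 ± 0.136, all called. CDKN1A (-0.01, adjusted p 0.939), DDIT3 (-0.18, adjusted p 0.21) and CYP3A4 (-0.15, adjusted p 0.863) did not pass. The test called 1580 genes higher and 1398 lower at the high dose, 1649 and 1539 at the medium dose and 1041 and 770 at the low dose. These counts depended on single libraries. The high count was 1300 without Samul-tang high replicate 2 and 1799 without replicate 3. The low count was 604 without Samul-tang low replicate 3, 693 without replicate 2 and 1047 without vehicle replicate 2. The medium count was 747 without replicate 2 and 4675 without replicate 3 of Samul-tang medium, and 261 when these groups were fitted alone. Replicates 2 and 3 of Samul-tang medium differed by 9.87 times counting noise, the most of any pair. They lay at 2.7 and -11.4 on the first principal component. The medium share of higher genes was 51.7%, and 63.5% with an offset for GC content and length.

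**Figure D1:**
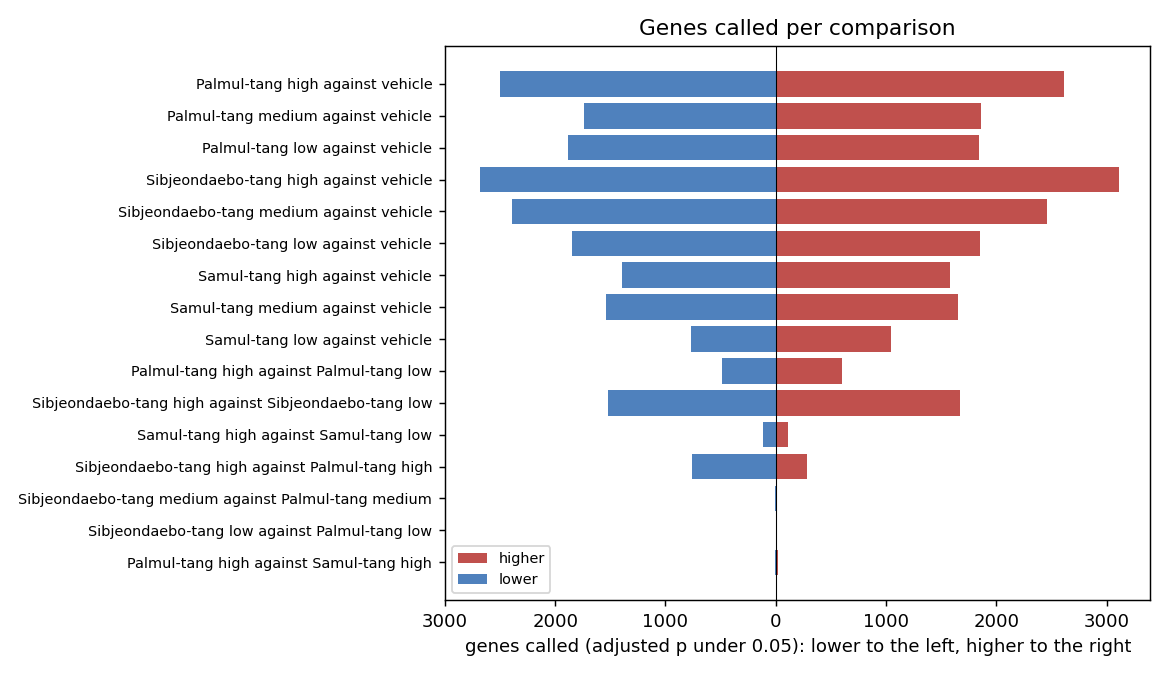
Genes called per comparison by edgeR's quasi-likelihood test at an adjusted p under 0.05. Bars to the right count genes higher in the group named before "against" and bars to the left genes lower there, from 5791 calls for Sibjeondaebo-tang high against vehicle to 0 for Sibjeondaebo-tang low against Palmul-tang low.

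High and low doses of the same formula were compared to follow the dose response without the vehicle libraries. NRF2 targets rose in every formula, in 19 of 22 members for Palmul-tang, 20 for Sibjeondaebo-tang and 17 for Samul-tang, with median log2 values of 0.47, 0.46 and 0.44. AKR1B10 rose by log2 1.63 ± 0.06, 1.36 ± 0.06 and 1.51 ± 0.073 in that order, and NQO1 by 1.02 ± 0.053, 0.88 ± 0.053 and 0.75 ± 0.064. CYP1A1 rose by 3.40 ± 0.083, 2.92 ± 0.081 and 1.93 ± 0.097, and ALDH3A1, an aldehyde dehydrogenase, by 2.03 ± 0.153, 1.58 ± 0.152 and 1.22 ± 0.194. Integrated stress response and amino acid response genes rose in 8, 16 and 5 of 22 members, and 1 fell with Sibjeondaebo-tang. Asparagine synthetase ASNS rose by 0.56 ± 0.05, 0.79 ± 0.05 and 0.52 ± 0.061, and the cystine transporter SLC7A11 by 1.00 ± 0.097, 0.90 ± 0.096 and 0.90 ± 0.118. SLC7A11 was also a member of the NRF2 list, and NQO1 of both the NRF2 and AHR lists, so these lists overlap. HSPA1A changed little with dose beside its difference from vehicle, where it was at 58.53 CPM. At the high and low dose it was at 124.5 and 131.1 CPM with Palmul-tang. It was at 126.4 and 115.6 CPM with Sibjeondaebo-tang and at 115 and 113.4 CPM with Samul-tang.

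Cholesterol synthesis genes fell with dose in 18 of 24 members for Palmul-tang (HMGCS1 -0.41 ± 0.045), 9 for Sibjeondaebo-tang, where 1 rose (-0.33 ± 0.045), and 7 for Samul-tang (-0.34 ± 0.055). The Sibjeondaebo-tang list had an adjusted p of 0.0642 with an estimated correlation. Metallothionein genes fell in 4, 7 and 1 of 9 members, with MT1F at -0.78 ± 0.128, -1.01 ± 0.128 and -0.81 ± 0.15. That list's adjusted p was 0.0552 with an estimated correlation for Sibjeondaebo-tang, and the others kept the call. Immediate early genes rose in 9, 11 and 1 of 21 members. Glycolysis and hypoxia genes rose in 11, 17 and 2 of 25 members, with adjusted p values of 0.131 for Palmul-tang and 0.118 for Sibjeondaebo-tang with an estimated correlation. With Palmul-tang and Samul-tang, genes for hepatocyte secreted proteins fell in 9 and 2 of 25 members, and 1 rose with Palmul-tang. On the log2 scale ALB fell by 0.31 with Palmul-tang, 0.30 with Sibjeondaebo-tang and 0.30 with Samul-tang, and the BMP-responsive gene ID3 by 0.92, 0.95 and 0.76. Bile acid genes fell in 4 of 13 members and rose in 1 with Palmul-tang, including CYP7A1, the rate-limiting enzyme of bile acid synthesis (-0.72 ± 0.145).

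The high dose differed from the low dose in 1091 genes for Palmul-tang (603 higher, 488 lower), 3191 for Sibjeondaebo-tang (1673 higher, 1518 lower) and 229 for Samul-tang (114 higher, 115 lower). The share of higher genes for Sibjeondaebo-tang was 52.4%, and it was 66.2% with an offset for GC content and length and 39.8% without the filter on low counts. Without that filter the Samul-tang count was 376, of which 61.2% were higher. These comparisons shared no libraries between formulas. Palmul-tang and Sibjeondaebo-tang shared 469 higher and 267 lower calls, beside 62.7 and 46.1 for independent lists, and 2 genes went opposite ways. Palmul-tang and Samul-tang shared 106 higher and 98 lower calls, beside 4.3 and 3.5. In all 3 formulas 97 genes were higher and 80 lower. Without Samul-tang low replicate 3 the Samul-tang count was 85, without low replicate 2 it was 108, without high replicate 2 it was 86 and without high replicate 3 it was 108. In the other formulas, without Palmul-tang low replicate 2 the Palmul-tang count was 702 and without Sibjeondaebo-tang high replicate 3 the Sibjeondaebo-tang count was 2042. Without Sibjeondaebo-tang low replicate 3, where fibroblast markers were measured, the Sibjeondaebo-tang count was 2428, the calls shared with Palmul-tang fell from 736 to 629 and those shared by all 3 formulas from 177 to 155. The number shared by all 3 formulas was 71 without Samul-tang low replicate 3, 94 without low replicate 2, 75 without high replicate 2 and 93 without high replicate 3.

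**Figure D2:**
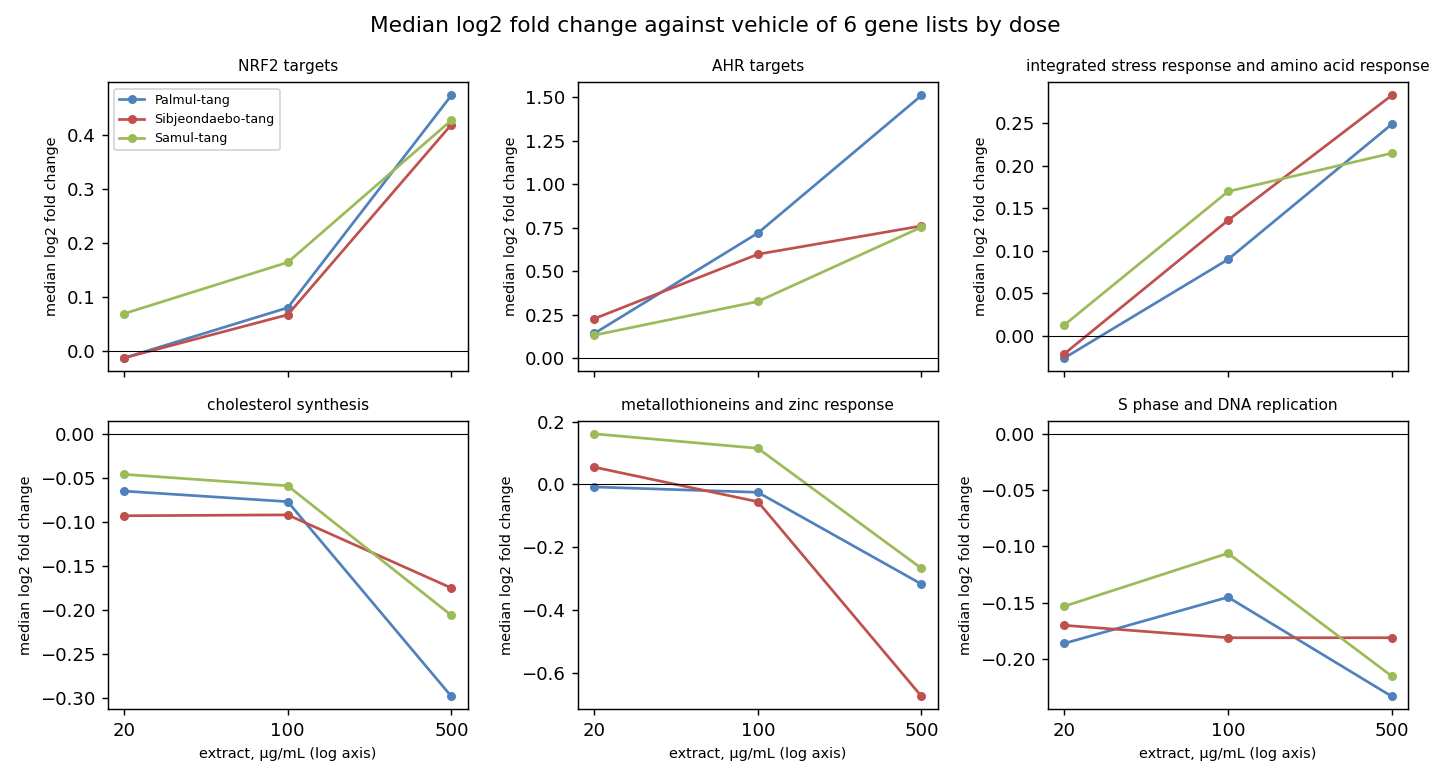
Median log2 fold change against vehicle (vertical axis) of 6 gene lists at 20, 100 and 500 µg/mL (horizontal log axis) of Palmul-tang, Sibjeondaebo-tang and Samul-tang. NRF2 targets reached medians of 0.47, 0.42 and 0.43 at the high dose, while S phase genes lay below 0 at every dose.

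**Figure D3:**
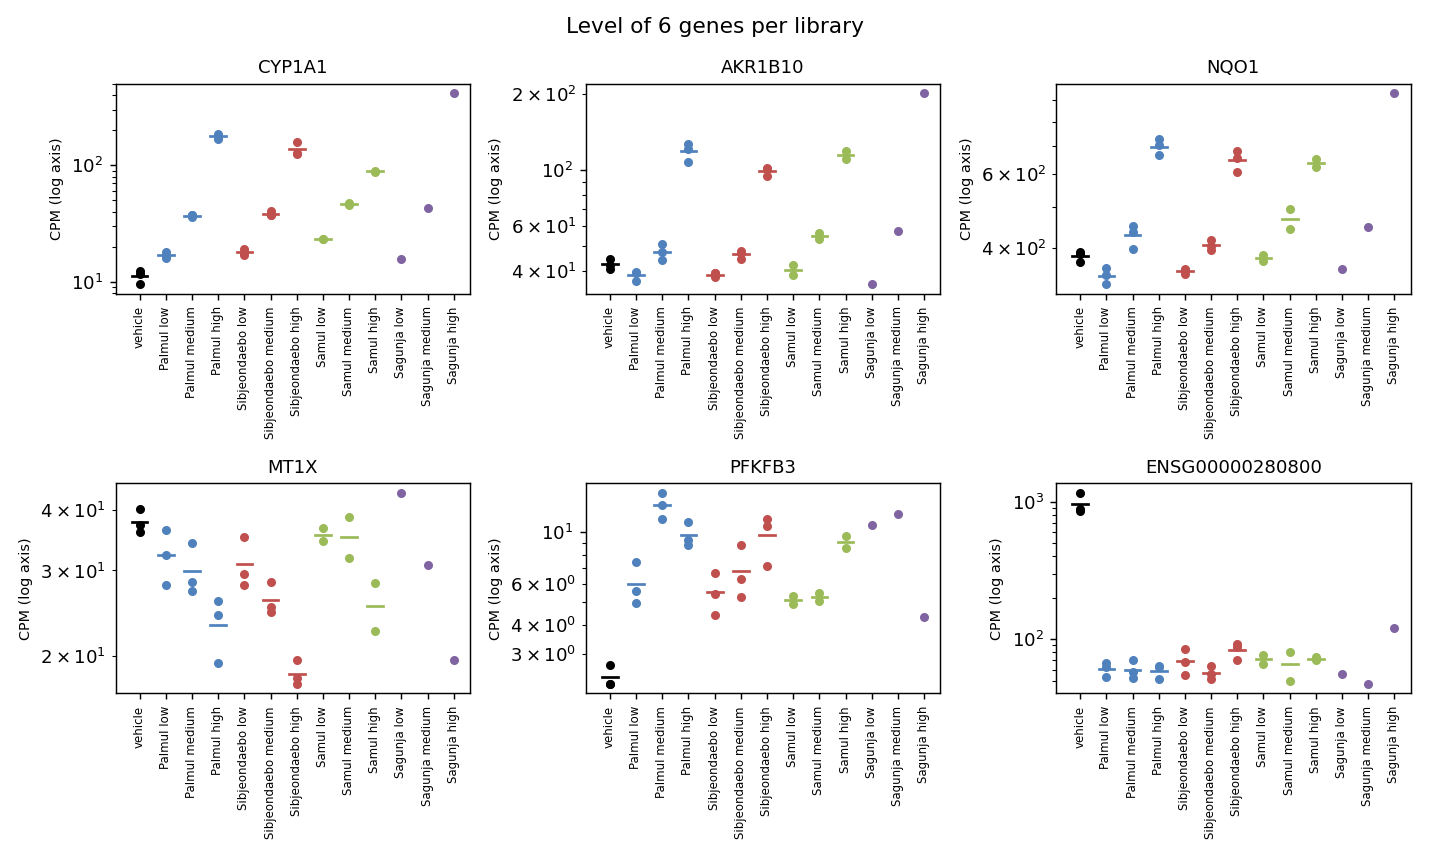
Level of 6 genes in CPM (vertical log axis) in each library, with dots for libraries and short lines for group means where a group had more than 1 library. CYP1A1 was highest at 500 µg/mL of each formula, and ENSG00000280800 was higher in the 3 vehicle libraries than in any other.

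Sibjeondaebo-tang was compared with Palmul-tang at matched doses of whole extract. The labels do not give the amount of each shared herb, so added herbs and other amounts of the shared herbs cannot be told apart. At the high dose 282 genes were higher and 759 lower in Sibjeondaebo-tang. Mitochondrial transcripts took 17.2% to 19.4% of counts in Sibjeondaebo-tang high and 14.9% to 16.9% in Palmul-tang high, and TMM factors ran from 0.919 to 0.957 and from 0.984 to 1.013. The lower genes included HERC2P3 (log2 -1.49 ± 0.106), GOLGA8B (-1.42 ± 0.071), TPM2, a tropomyosin (-1.35 ± 0.122), GOLGA8A (-1.33 ± 0.09), the collagen gene COL7A1 (-1.31 ± 0.132), MST1P2 (-1.29 ± 0.122), HERC2P2 (-1.26 ± 0.076) and PABPC1L (-1.14 ± 0.069). The HERC2, GOLGA8 and MST1 genes have near-identical copies and are uncertain. Of the called genes, 3 rose and 49 fell by at least 1 on the log2 scale. Among genes that met the naming limits on level, replicates and symbol, the higher ones included MFSD4B at 0.57 ± 0.139, GPC6 at 0.34 ± 0.067 and FAM222A at 0.32 ± 0.082. C1orf116 (0.47 ± 0.122), MT-ND4L (0.44 ± 0.116), AK4P1 (0.37 ± 0.106), RHBDL2 (0.35 ± 0.109) and PPP1R3D (0.35 ± 0.098) passed. Apart from GPC6, each of these higher genes lost the call without at least 1 replicate. CYP1A1 was lower in Sibjeondaebo-tang high (-0.38 ± 0.071, adjusted p 7e-04). NQO1 (-0.11, adjusted p 0.243), HMOX1 (-0.02, adjusted p 0.883), MT1X (-0.33, adjusted p 0.151), ALB (0.06, adjusted p 0.564), CDKN1A (-0.04, adjusted p 0.741), DDIT3 (-0.18, adjusted p 0.282) and CYP3A4 (-0.02, adjusted p 0.987) did not pass. The count was 545, of which 8.07% were higher, without Sibjeondaebo-tang high replicate 3 and 675 without Palmul-tang high replicate 1. The share of higher genes depended on the setting, at 27.1% as reported, 15% with median-ratio factors, 17% without the filter on low counts, 14.9% with the compared groups alone and 48.7% with an offset for GC content and length added after seeing the data.

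By list at the high dose, 5 of 31 were called with the preset correlation and 0 with an estimated one. Cholesterol synthesis genes were higher in Sibjeondaebo-tang in 5 of 24 members and bile acid genes in 1 of 13, and AHR targets were lower in 1 of 9, each with an adjusted p of 0.151 with an estimated correlation. At the medium dose 5 genes were called, PDK1 (log2 -0.38 ± 0.051), PFKFB4 (-0.43 ± 0.076), BHLHE40 (-0.50 ± 0.068), TMCC1 (-0.40 ± 0.063) and the lipid droplet gene PLIN2 (-0.29 ± 0.051), all lower in Sibjeondaebo-tang. The count was 168 without the filter on low counts, of which 39.9% were higher, 24 with DESeq2, 26 with the replicate block and 7 with the compared groups alone. The glycolysis and hypoxia list was lower there (median log2 -0.23, 2 of 25 members called, adjusted p 0.0307 with an estimated correlation). Mitochondrial transcripts took 14.9% to 16.9% of counts in Palmul-tang medium and 15.7% to 19.7% in Sibjeondaebo-tang medium. With 1 library left out, the count was 30 without Sibjeondaebo-tang medium replicate 1, 3 without Palmul-tang medium replicate 3, and 2 without Palmul-tang medium replicate 1, Sibjeondaebo-tang medium replicate 2 or replicate 3. At the low dose edgeR called 0 genes, with 338 at an unadjusted p under 0.05 where 804 are expected by chance, and DESeq2 also called 0. Without the filter on low counts edgeR called 72, and with the compared groups alone 3. Without Sibjeondaebo-tang low replicate 3, the library with fibroblast markers, edgeR called 0 with 287 at an unadjusted p under 0.05.

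Palmul-tang high was compared with Samul-tang high to see what accompanied the wider herb mixture, across library sets. The test called 23 genes higher and 7 lower, a share of 76.7% higher that depended on the setting. It called 261 without the filter on low counts, of which 35.6% were higher, 46 with the replicate block (56.5% higher) and 51 with DESeq2. CYP1A1 was higher in Palmul-tang (log2 1.01 ± 0.082, adjusted p 2.2e-08), as were ALDH3A1 (0.78 ± 0.149), EGR1 (0.56 ± 0.087), DUSP6 (0.34 ± 0.055) and FOSL2 (0.35 ± 0.076), while CEBPA was lower (-0.30 ± 0.054). The lists of AHR targets (2 of 9 called), immediate early genes (3 of 21) and ER chaperones (0 of 19) were higher, with adjusted p values of 0.00126, 0.00554 and 0.0329 with an estimated correlation. Without Samul-tang high replicate 2 the count was 2, without its replicate 3 it was 10, and without Palmul-tang high replicate 1 or 2 it was 14.

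Calls against the shared vehicle libraries overlapped between formulas. At the high dose Palmul-tang and Sibjeondaebo-tang shared 2035 higher and 1576 lower calls, beside 505.7 and 417.2 for independent lists and a mean of 0 in 20 simulations of unchanged groups, which hold no effects and so are no yardstick for this count. Palmul-tang and Samul-tang shared 1409 and 1241 calls, beside 257 and 217.5, and Sibjeondaebo-tang and Samul-tang shared 1274 and 1026, beside 305.4 and 233.1. The covariances of log2 fold changes across genes were 0.181, 0.16 and 0.161, and the simulated covariances were 0.00835, 0.0119 and 0.0115. The simulated groups were drawn around the mean of these same vehicle libraries. The simulation therefore leaves out the covariance that a shared vehicle creates, and it cannot show how large that part is. Genes are not independent replicates, and part of the excess may come from the shared vehicle libraries, which could not be split with 2 in each part. At the low dose against vehicle the covariances were 0.143, 0.121 and 0.126 in the same order. Between high and low dose, where formulas shared no library, they were 0.0382, 0.0234 and 0.0212. Much of the covariance against vehicle was therefore present at 20 µg/mL already. At all 9 doses 434 genes were called higher and 311 lower than vehicle. This total of 745 was 181 when each comparison was fitted on its 2 groups alone. It was 355 without Samul-tang low replicate 3, 381 without its replicate 2, 453 without Samul-tang medium replicate 2, 444 without vehicle replicate 2 and 679 without Sibjeondaebo-tang low replicate 3.

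Sagunja-tang had 1 library per dose and no replicate check, so no test between groups was made. The percentiles given here place a list among random lists in the same single libraries and carry no spread between libraries. In the high-dose library CYP1A1 was at 417 CPM, beside 42.9 at the medium dose, 15.7 at the low dose and 11.3 ± 1.51 (SD, n = 3) in vehicle. AKR1B10 was at 201, 57.3 and 35.5 CPM beside 42.5 ± 2.02 in vehicle, NQO1 at 936, 450 and 357 beside 383 ± 11, and SLC7A11 at 80.4, 38.4 and 30.3 beside 27.9 ± 2.46. Against the mean of vehicle, the high-dose median of NRF2 targets was log2 0.66, above 100% of 10000 random lists matched on expression, with 21 of 22 members above 0. The AHR target median was 1.29, the metallothionein median -0.74 and the cholesterol synthesis median -0.34, at percentiles of 100, 0 and 0. From the low to the high dose the NRF2 median changed by 0.65, the AHR target median by 1.195, the metallothionein median by -1.05, the cholesterol synthesis median by -0.38 and the glycolysis and hypoxia median by -0.26. Against vehicle the glycolysis and hypoxia median was above 0 at each dose, at 0.21, 0.52 and 0.43 with the high, medium and low dose, each at percentile 100. The ER chaperone median was alike at each dose, at 0.213, 0.206 and 0.225 in that order, and the heat shock median was 0.246, 0.278 and 0.294. For S phase and DNA replication genes the median was -0.149, -0.116 and -0.155 in that order. From the low to the high dose it changed by 0.015. The metallothionein median was 0.41 with the low dose, with 9 of 9 members above 0, and 0.01 with the medium dose. The blood and immune marker list had a median of 0.47 against vehicle in the high-dose library, at percentile 99.9, with 4 of 5 members above 0. LYZ was at 1691, 1420 and 1018 CPM beside 1226 ± 61.1, and CD68 at 82.1, 64.5 and 59.6 beside 53.03 ± 2.60. MT1X was at 19.7 CPM with the high dose and 43.3 CPM with the low dose.

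Markers of other cell types were measured in the 30 libraries. All 8 lung and squamous epithelium markers were under 1 CPM in every library, as were 7 of 8 endothelial, 8 of 12 blood and immune, 9 of 10 muscle and neuron and 5 of 10 fibroblast markers. The highest gene of each of these last 4 lists was PECAM1 at 2.35 CPM, LYZ at 1758 CPM, TUBB3 at 147 CPM and COL1A1 at 8.3 CPM, in that order. Medians over all libraries were 1445 CPM for LYZ, 63.9 CPM for CD68 and 5.58 CPM for the fibroblast marker PDGFRB. The fibroblast markers COL1A1 (8.3 CPM), COL1A2 (6.97 CPM), COL3A1 (4.31 CPM) and DCN (1.9 CPM) were over 1 CPM in 1 library, Sibjeondaebo-tang low replicate 3, and under 1 CPM in the others.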

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

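Of the tests reported in this part, the alternatives for genes called at all 9 doses and the tests of the dose response, the library set, a single library and other splits of the libraries were chosen after the results they measure had been seen. The correction for GC content and length and the test of intron-retaining transcripts were added after the called genes had been seen. For that correction and that test alone, what each would show was written before its values were computed.

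Results stood out here because formulas differed in a direct test. Sibjeondaebo-tang high differed from Palmul-tang high in 1041 genes, and the medium doses differed in 5. The glycolysis and hypoxia list was called lower at the medium dose of Sibjeondaebo-tang, with 2 of 25 members called and an adjusted p of 0.0307 with an estimated correlation, while another split of these 6 libraries called 400 genes beside 7 for the real one. Palmul-tang high differed from Samul-tang high in 30 genes, with list p values of 0.00126 for AHR targets, 0.0329 for ER chaperones and 0.00554 for immediate early genes. In that comparison the formula cannot be told apart from the library set. Among named genes of Sibjeondaebo-tang high against Palmul-tang high, log2 fold changes were -1.31 for COL7A1, -1.494 for HERC2P3, -1.42 for GOLGA8B, -1.349 for TPM2, -1.332 for GOLGA8A, -1.286 for MST1P2, -1.257 for HERC2P2 and -1.143 for PABPC1L. They were 0.574 for MFSD4B, 0.468 for C1orf116, 0.437 for MT-ND4L, 0.366 for AK4P1, 0.353 for RHBDL2, 0.351 for PPP1R3D, 0.339 for GPC6 and 0.323 for FAM222A.

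A shared difference from vehicle at every dose was the main open pattern, with 745 genes called the same way at all 9 doses, 181 when each comparison was fitted on its 2 groups alone and 355 without Samul-tang low replicate 3. Whether their response grew with the dose stays open, because they were chosen as called at every low dose; the median ratio of the absolute log2 fold change at the high dose to the low dose was 1.16, 1.15 and 1.08 for Palmul-tang, Sibjeondaebo-tang and Samul-tang, the upper quartiles were 1.41, 1.48 and 1.3, and 100, 170 and 25 of the genes were called between these doses. GC content and gene length are not the whole cause, since 671 of the 745 genes were still called the same way at all 9 doses after that correction. A difference between library sets and the extracts cannot be told apart here, because 0 extract libraries shared the label set of the vehicle, and MALAT1 was at 391 to 426 CPM in vehicle and 235 to 336 CPM in every extract library. The label set is a prefix of the sample label whose meaning is not given, while the titles name the same batch for vehicle and extracts. A response already complete at 20 µg/mL also stays open and was not tested.

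The difference between Sibjeondaebo-tang high and Palmul-tang high was weighed next. After correction for GC content and length 964 of the 1041 genes were still called the same way. The correction called 1527 genes in all, with 48.7% higher in place of 27.1%, so the excess of lower genes depended on it. Mean GC content was 52.4% in the lower genes, 46.2% in the higher genes and 49.4% in all genes with annotation. Without any 1 library at least 545 genes were called, although the lowest count is close to 0.5 of the full one. In the 755 lower genes with annotation, a mean of 23.2% of annotated transcripts were of the retained-intron type, against 16.8% in matched random sets. This was at percentile 100, and still at percentile 100 when also matched on GC content. The 281 higher genes were at 12.2% against 15.9%, at percentile 0. These are shares of annotated transcript models, and no transcript level was measured here. Lower genes at the high against the low dose were at percentile 100 for Sibjeondaebo-tang and 57.15 for Palmul-tang. For Samul-tang, with 115 lower genes, they were at 99.45, and at 97.65 when also matched on GC content. Whether the enrichment was limited to Sibjeondaebo-tang is therefore not settled. A lower yield of intron-retaining transcripts in Sibjeondaebo-tang high than in Palmul-tang high is a candidate explanation, and whether it would come from RNA handling or from the cells was not tested; NEAT1, a nuclear RNA, was at 134 ± 10.7 and 248 ± 1.55 CPM in these groups, while MALAT1, also nuclear, was at 317 ± 25.7 and 273 ± 14.0.

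Other splits of the 6 libraries were counted in fits of the compared groups alone. With 10 splits of 3 against 3 the share cannot fall under 0.05. The real split and the highest other split called 5152 and 0 genes for Palmul-tang high against vehicle, 3772 and 1 for medium, 4060 and 1 for low, 5939 and 0 for Sibjeondaebo-tang high, 5180 and 0 for medium and 4888 and 1 for low. For high against low dose they called 930 and 0 for Palmul-tang and 3822 and 1 for Sibjeondaebo-tang. For Sibjeondaebo-tang against Palmul-tang they called 909 and 3 at the high dose, 7 and 400 at the medium dose and 3 and 5 at the low dose. In these 11 comparisons 1 split was as large as the real one, the real one itself, except for 2 at the medium dose and 3 at the low dose of Sibjeondaebo-tang against Palmul-tang. The split with 400 genes set Palmul-tang medium replicates 1 and 2 with Sibjeondaebo-tang medium replicate 1 against the others. Mitochondrial transcripts took 14.9%, 14.9% and 15.7% of counts in these 3 libraries and 16.9%, 18.5% and 19.7% in the others, and what set them apart was not tested.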

How the results depend on the processing

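The offset for GC content and length, the prior count for Sagunja-tang high against low, and all alternatives for the calls shared at all 9 doses and in high against low were chosen after the results were seen, and the other alternatives before. Median-ratio factors and that offset moved none of the 16 gene counts by over 1.5 times, and a prior count of 0.5 moved none of the 12 Sagunja-tang values against vehicle past the spread between vehicle libraries. From the low to the high dose of Sagunja-tang it moved the AHR target median from 1.195 to 1.392. Without Sibjeondaebo-tang low replicate 3, which held fibroblast marker transcripts, 679 genes were called the same way at all 9 doses (745 in full), and high against low shared 155 calls over the 3 formulas (177) and 629 between Palmul-tang and Sibjeondaebo-tang (736). The 745 became 181 with the compared groups alone. With 1 library left out they ran from 355 without Samul-tang low replicate 3 to 925 without Samul-tang medium replicate 3, the 177 from 71 without Samul-tang low replicate 3 to 175 without Palmul-tang low replicate 1, and the 736 from 507 to 635. Without a filter on low counts the test called 376 genes for Samul-tang high against low, 168 for Sibjeondaebo-tang medium against Palmul-tang medium, 72 for the low doses and 261 for Palmul-tang high against Samul-tang high. The compared groups alone gave 261 for Samul-tang medium against vehicle and 3 for Sibjeondaebo-tang low against Palmul-tang low. DESeq2 called 24 genes for Sibjeondaebo-tang medium against Palmul-tang medium and 51 for Palmul-tang high against Samul-tang high. Deviations of same-numbered libraries from their group means correlated from -0.17 to 0.11 over all tested genes. No pairing by replicate number was seen across genes as a whole, while an effect on part of the genes stays open. The replicate block gave 26 and 46 in the comparisons named for DESeq2 and 2 lists for Sibjeondaebo-tang low against Palmul-tang low. Other counts stayed within 1.5 times. With an estimated correlation the lists called against vehicle were 5 for Palmul-tang medium, 3 for low, 5 for Sibjeondaebo-tang high, 4 for medium, 3 for low, 3 for Samul-tang medium and 3 for low. They were 4 for Sibjeondaebo-tang high against low, 0, 1 and 0 for Sibjeondaebo-tang against Palmul-tang at high, medium and low dose, and 3 for Palmul-tang high against Samul-tang high. Calls of at least 2-fold shared at the high dose were 142 for Palmul-tang and Sibjeondaebo-tang, 91 for Palmul-tang and Samul-tang and 81 for Sibjeondaebo-tang and Samul-tang, as fewer genes pass that limit. The cause of the other changes was not tested.

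The share of higher calls moved by over 10 points under some settings. Without the filter it was 39.8% (52.4% as reported) for Sibjeondaebo-tang high against low, 61.2% (49.8%) for Samul-tang high against low, 17% (27.1%) for Sibjeondaebo-tang high against Palmul-tang high and 35.6% (76.7%) for Palmul-tang high against Samul-tang high. With the GC and length offset it was 63.5% (51.7%) for Samul-tang medium against vehicle and 66.2% for Sibjeondaebo-tang high against low. With that offset it was also 63.8% (53.7%) for Sibjeondaebo-tang high against vehicle and 48.7% for Sibjeondaebo-tang high against Palmul-tang high. The compared groups alone gave 14.9% for Sibjeondaebo-tang high against Palmul-tang high, and the replicate block gave 56.5% for Palmul-tang high against Samul-tang high.

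Leaving out 1 library at a time left a lone sample in some Samul-tang groups, which is then assumed to vary like the other groups. Counts against vehicle ran from 3798 to 4612 for Palmul-tang high, 2309 to 3424 for medium and 2392 to 3187 for low. They ran from 4305 to 5126 for Sibjeondaebo-tang high, 3474 to 4487 for medium and 2284 to 3156 for low, and from 1300 to 2387 for Samul-tang high, 747 to 4675 for medium and 604 to 1436 for low. High against low ran from 702 to 827 for Palmul-tang, 2042 to 2582 for Sibjeondaebo-tang and 85 to 108 for Samul-tang. Sibjeondaebo-tang against Palmul-tang ran from 545 to 925 at the high, 2 to 30 at the medium and 0 to 0 at the low dose, where edgeR called 0 genes in full with 338 at an unadjusted p under 0.05 and DESeq2 called 0. Palmul-tang high against Samul-tang high ran from 2 to 21. Of 688 alternative values for 64 named results, 643 kept direction and call, 45 lost the call and 0 reversed. The named results had been picked for large changes with separated replicates in these same libraries, so a reversal was unlikely from the start. At this depth the test on simulated counts recovered 32% of genes changed 1.2-fold for Palmul-tang high against vehicle, so smaller changes were often not detectable.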

Other observations

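The genes in this part were chosen after their values were seen. PLIN2, which coats lipid droplets, was higher at the high than the low dose of each formula, by log2 0.31 ± 0.051 for Palmul-tang, 0.38 ± 0.051 for Sibjeondaebo-tang and 0.26 ± 0.062 for Samul-tang, all called by edgeR. Mitosis genes were higher than vehicle in 14 of 27 members and lower in 1 at the medium dose of Palmul-tang, with an adjusted p of 0.184 with an estimated correlation. Nuclear respiratory chain genes were lower in 12 of 24 members and higher in 1 at the low dose of Sibjeondaebo-tang, with an adjusted p of 0.637 with an estimated correlation.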
